A study of Arabidopsis thaliana with 16 samples.

How the data were processed

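RNA of whole seedlings from 16 samples, 2 of each of 8 genotypes, was measured by strand-specific mRNA sequencing. Per the submitters' processing notes, reads were aligned to TAIR10 with HISAT2 2.0.4 and counted per gene with HTSeq 0.6.1p1. The deposited counts are raw whole numbers for 32833 genes, of which 6161 had 0 counts in all libraries. The FPKM values deposited by the authors equal counts over gene length and a library constant that lies within 0.666% of the TMM scaling, and they were not used further. The strand setting and the treatment of reads with several alignments were not given in the sources used here. Of the gene identifiers, 32548 matched a locus of the reference annotation, 32532 of them with the same start and end. NUP50C was taken as AT4G11790, which the annotation describes as a Nup50 protein with a Ran-binding domain.

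Depth ranged from 37923632 to 46194172 counts per library, and between 23240 and 23556 genes had at least 1 count. The filterByExpr function of edgeR 4.0.16 (R 4.3.3), with its minimum count of 10, left 22427 genes, 21536 of them protein coding, with 100.0% of all counts. A count of 0 was read as allowing up to 3 counts in each library, and intervals are exact at 95%. Such floors and intervals cover counting error only. Where the reference group had 0 counts, a fold is a lower bound against that floor, and where it had 1 to 3 counts over its libraries it is a ratio with a counting interval. The common biological coefficient of variation was 0.102. Within genotypes the spread between libraries was 5.08 to 17.5 times that of counting alone (chi-square per degree of freedom), lowest in the triple mutant and highest in the libraries labelled nup82 nup136, and Pearson r across genes was 0.981 to 0.986.

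All 16 libraries entered 1 edgeR quasi-likelihood fit with robust estimation, TMM scaling and 1 coefficient per genotype, which left 8 residual degrees of freedom. The 14 contrasts were each of the 7 mutants against WT, the triple mutant against each of the 3 double mutants, and 4 terms of non-additivity on the log2 scale (a double mutant minus its single effects, and the three-way term). P-values were adjusted by Benjamini-Hochberg over all tested genes, and genes at an adjusted p under 0.05 count as higher or lower, as risen or fallen. CPM are scaled by TMM. The effect of each mutation was compared between its 4 backgrounds by Pearson r across genes, so that no library entered both sides of a pair. No replicate block was used, since the labels do not say that a replicate number marks a shared batch.

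The design, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. Named are the 3 mutated genes, the 10 protein-coding genes with the largest rise and fall in the triple mutant against WT, 5 each way in other comparisons, and up to 4 per list and comparison. Apart from the mutated genes and list members, they needed a mean of at least 1 CPM over the 16 libraries. In comparisons with WT they also had to be protein coding, with both libraries of 1 group beyond both of the other. List members needed only to pass the threshold. Members named beyond this rule, such as those that moved against their list, were chosen after their values were seen. The 28 lists held 524 genes, 497 of them tested, for the nuclear pore, transport, defence and hormone pathways, nutrients, photosynthesis, stress, cell division and markers of organs, seeds and pollen. The 27 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom weights, with a preset correlation of 0.01, adjusted over 189 tests against WT, 81 for the third mutation and 108 of non-additivity. List counts in brackets are adjusted over the list alone. The estimated correlation, fry and a replicate block were alternatives. List medians with genes at the floor set at their bounds are given where they differ from the fitted ones.

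Alternatives to the main settings were DESeq2 size factors, library totals as the only scaling (added after the data were seen), no filter on low counts, the Wald test of DESeq2 1.42.0, a fit of only the 2 genotypes compared, a replicate block, an absolute log2 fold change of at least 1, and each library left out in turn. The steps were tested on simulated data with known changes. The genes changed 1.5-fold, 2-fold and 4-fold were drawn from those above a minimum mean level, with a spread that followed the trend over all genes. The calls therefore do not cover genes of low level or of larger spread. Against WT, 56 of 67 genes changed 1.5-fold, 63 of 67 changed 2-fold and 66 of 66 changed 4-fold were called, with 6 false calls among 22127 genes. In the three-way term the calls were 9 of 67, 33 of 67 and 65 of 66, with 4 false calls among 22197. A photosynthesis list lowered 1.5-fold gave an adjusted p of 5.51e-175, or 1.66e-07 with an estimated correlation, and 0 of 26 other lists passed. Genes that vary together were not simulated, so the 0 does not test the preset correlation. Over 100 simulated genes, all changed 2-fold by nup136 in every background, the median r was 0.979 for nup136, -0.0591 for nup50c and -0.0467 for nup82. These are no reference for r over all tested genes. Figures were drawn with matplotlib 3.10.9. Splicing, allele sequences and the place of transcripts in the cell were not analysed, since counts per gene do not hold them.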

Results

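Strand-specific mRNA sequencing covered whole 9-day-old seedlings of Arabidopsis thaliana grown on medium with sucrose, without treatment. The 16 libraries fall into 8 genotypes with 2 libraries each: wild type (WT), nup50c, nup82, nup136, their 3 pairwise combinations and the triple mutant nup50c nup82 nup136. The mutated genes encode proteins of the nuclear basket, the part of the nuclear pore complex that faces the nucleoplasm and takes part in the passage of RNA and proteins. Each library held between 37923632 and 46194172 gene counts, and 22427 of 32833 genes had enough counts to be tested. The labels do not say whether the 2 libraries of a genotype came from separate cultures, so every p-value measures only the spread between these samples. Positions are on TAIR10, and every mean is over n = 2 libraries with its SD.

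The transcripts of the 3 mutated genes were examined first in every genotype. NUP50C (AT4G11790, chromosome 4, 7090313 to 7093492) stood at 42.0 ± 1.89 CPM (counts scaled to library size) in WT and fell to 14.1 ± 1.29 in nup50c, 8.88 ± 0.157 in nup50c nup82, 12.1 ± 3.29 in nup50c nup136 and 11.1 ± 0.176 in the triple mutant (adjusted p = 4.27e-08, 6.32e-11, 2.33e-10 and 1.18e-11). The first 3 are 33.5%, 21.2% and 28.8% of WT. NUP136 (AT3G10650, chromosome 3) stood at 47.9 ± 1.59 CPM in WT and fell to 20.7 ± 1.57 in nup136, 20.3 ± 0.524 in nup50c nup136, 28.7 ± 7.43 in nup82 nup136 and 19.4 ± 1.12 in the triple mutant (adjusted p = 3.58e-07, 9.64e-08, 0.000105 and 8.49e-09). The libraries labelled nup82 nup136 held 33.9 and 23.4 CPM of NUP136. NUP82 (AT5G20200, chromosome 5, 6816612 to 6821827) did not follow the labels in the same way. It fell from 32.2 ± 3.86 CPM in WT to 21.6 ± 0.164 in the libraries labelled nup82, 66.9% of WT (adjusted p = 0.00563). It stood at 29.0 ± 3.06 in those labelled nup50c nup82, 27.5 ± 2.18 in those labelled nup82 nup136 and 37.1 ± 0.581 in those labelled nup50c nup82 nup136, that is 89.8%, 85.3% and 115% of WT (adjusted p = 0.614, 0.15 and 0.124). Counts cover whole genes, so transcripts of a disrupted allele are not separated from intact ones. In these 3 multiple mutants NUP82 did not pass the test, so directions below that involve nup82 there rest on the labels.

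**Figure D1:**
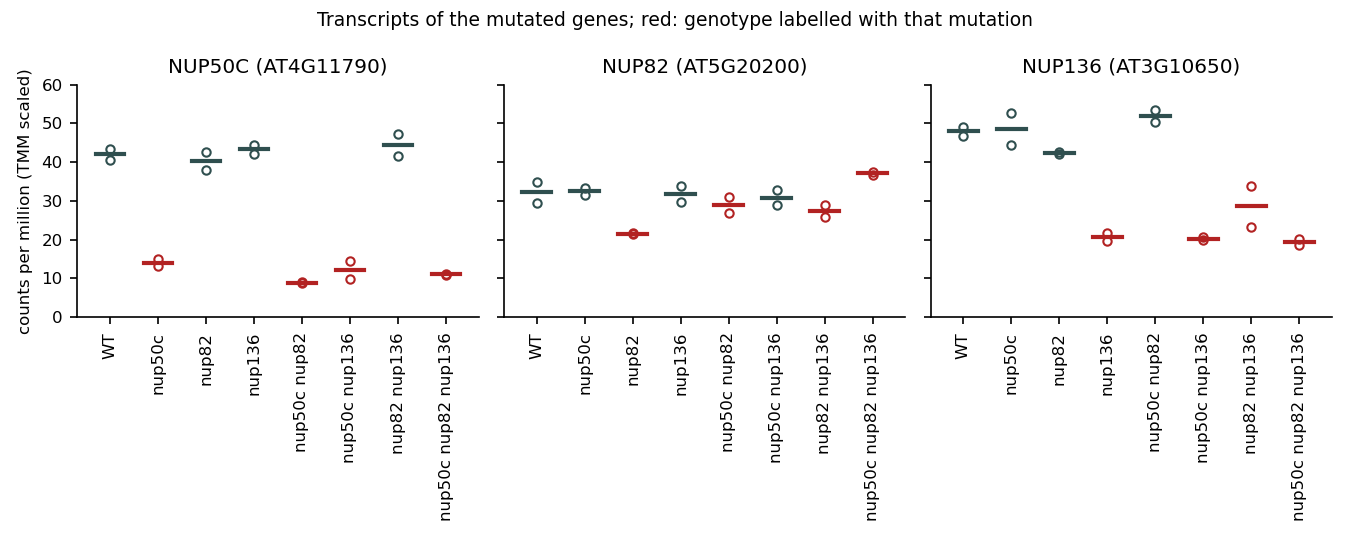
CPM of NUP50C, NUP82 and NUP136 (vertical axes) in the 8 genotypes, with circles for libraries, lines for the mean of 2 and red for genotypes labelled with that mutation. NUP50C and NUP136 were lower in all 4 genotypes labelled with their mutation, whereas NUP82 reached 115% of WT in the libraries labelled nup50c nup82 nup136.

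Compared with WT, the genotypes spanned a wide range of change. The numbers of higher and lower genes were 207 and 182 in nup50c, 192 and 120 in the libraries labelled nup82, and 126 and 77 in those labelled nup50c nup82. They were 1471 and 1757 in nup136, 2623 and 2927 in nup50c nup136, 1784 and 2541 in the libraries labelled nup82 nup136, and 5229 and 5445 in the triple mutant, 47.6% of the genes tested. With library totals as the only scaling, an alternative added after the data were seen, the larger direction turned in 4 genotypes: the numbers were 1833 and 1398 in nup136, 3147 and 2569 in nup50c nup136, 2594 and 2113 in the libraries labelled nup82 nup136, and 5498 and 5253 in the triple mutant. In the triple mutant it also turned without the low-count filter (5501 and 5401) and in a fit of only the 2 genotypes compared (5979 and 5789). In nup50c it turned without WT replicate 2 (67 and 108) and without nup50c replicate 1 (121 and 140). Calls of single genes depended on single libraries as well: of 3880 values with 1 library left out, 977 lost their call and 1 gained it. Nearly all of these values were picked for their calls, which favours losses over gains. No list test against WT held with an estimated correlation, so what is said of lists below covers the members counted. The first principal component held 40.8% of the variance and placed the triple mutant at 95.3 and 95.7, nup50c nup136 and the libraries labelled nup82 nup136 between 28.7 and 36.7, nup136 at -12.2 and -5.18, and WT at -40.3 and -39.1.

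**Figure D2:**
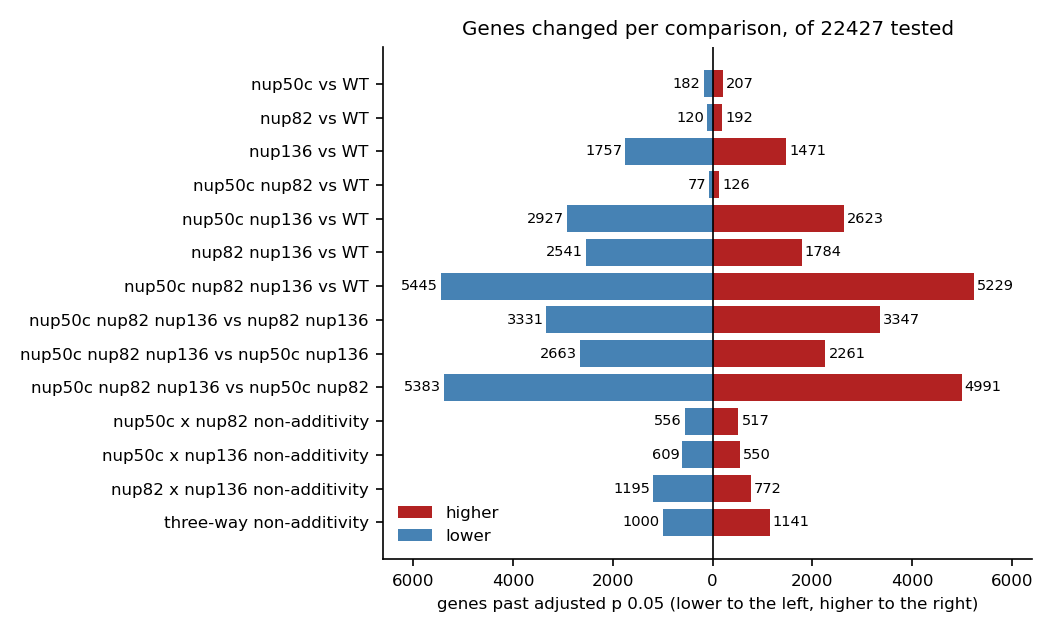
Number of genes higher (right) and lower (left) at an adjusted p of 0.05 in each comparison, of 22427 tested. The triple mutant differed from WT in 10674 genes and the libraries labelled nup50c nup82 in 203.

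In nup50c, a few genes of jasmonate, glucosinolate and salicylic acid lists rose. GSTU3, a glutathione S-transferase, rose 60.3-fold (counting interval 16.4 to 503) and PCR1, a membrane protein of cadmium resistance, 27.8-fold (4.22 ± 0.343 against 0.156 ± 0.156 CPM, adjusted p = 0.00326). ORA47, an ERF transcription factor of the jasmonate and wound response, rose 7.49-fold (14.1 ± 0.0507 against 1.87 ± 0.356 CPM, adjusted p = 2.24e-07), AT1G10585, a bHLH transcription factor, 11.9-fold and AT1G57630, a TIR-domain protein, 6.72-fold. NAS2, a nicotianamine synthase, fell 3.86-fold (adjusted p = 0.0106), the protease gene AT4G16563 2.95-fold, AT2G14247 3.82-fold and AT1G72416 2.23-fold. Of jasmonate response genes, 6 of 19 rose and 0 fell (10 and 0 adjusted over the list alone), with JAZ7, a repressor of the pathway, at a log2 fold change of 2.18 ± 0.30, JAZ5 at 1.38 ± 0.33 and the lipoxygenase LOX4 at 1.02 ± 0.23. The median was 0.60 (camera adjusted p = 1.42e-12, adjusted p = 0.195 with an estimated correlation). Of glucosinolate synthesis genes, 5 of 14 rose and 0 fell (11 and 0), among them FMOGS-OX1 at 0.96 ± 0.13 and the regulator MYB29 at 0.56 ± 0.14. This list's median was 0.35 (adjusted p = 1.86e-14, and adjusted p = 0.190 with an estimated correlation). Of salicylic acid defence genes, 3 of 30 rose and 0 fell (8 and 0), among them PBS3, an enzyme of salicylic acid synthesis, at 2.05 ± 0.41. Salicylic acid defence genes had a median of 0.26 (adjusted p = 9.84e-05, and adjusted p = 0.270 with an estimated correlation). These defence genes differed between the libraries of the genotype: PR1, a salicylic acid marker, stood at 24.4 and 3.48 CPM, against 0.362 and 0.0532 in WT, and did not pass the test. The total of 389 genes became 150 without WT replicate 1, 175 without WT replicate 2 and 95 without nup50c replicate 2, and 855 without the low-count filter. The jasmonate count became 1 without WT replicate 2, 1 without nup50c replicate 1 and 3 without nup50c replicate 2, the glucosinolate count 3 without WT replicate 2, 3 without nup50c replicate 1 and 2 without nup50c replicate 2 and the salicylic acid count 1 without nup50c replicate 1.

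In the libraries labelled nup82, AT2G41980, a SINAT-like ubiquitin ligase gene (chromosome 2, 17523071 to 17526126), fell 36.3-fold (0.516 ± 0.0159 against 18.8 ± 0.439 CPM, adjusted p = 8.47e-14). XPL1, the phosphoethanolamine N-methyltransferase of phosphocholine synthesis, fell 2.26-fold (121 ± 3.12 against 273 ± 23.9 CPM, adjusted p = 2.64e-09), MAF5, a MADS-box repressor of flowering, 2.50-fold, the protease gene AT4G16563 2.40-fold and GLP4, a germin-like protein, 2.31-fold. GSTU3 rose 31.9-fold (counting interval 8.48 to 269), PCR1 18.3-fold (adjusted p = 0.0110), AT1G57630 10.4-fold, LHT7, of an amino acid transporter family, 5.40-fold (adjusted p = 0.00131) and AT3G55646 4.49-fold. Of salicylic acid defence genes, 5 of 30 rose and 0 fell (6 and 0 adjusted over the list alone), with LURP1 at a log2 fold change of 1.87 ± 0.35 and AED1, an aspartyl protease, at 1.81 ± 0.43. The median was 0.41 (camera adjusted p = 1.16e-05, adjusted p = 0.244 with an estimated correlation). Of phosphate starvation genes, 3 of 15 rose and 0 fell (10 and 1), with the phosphatase PS2 at 1.27 ± 0.21 and the galactolipid synthase MGD3 at 1.22 ± 0.27. This list's median was 0.67 (adjusted p = 1.61e-09, and adjusted p = 0.261 with an estimated correlation). Of jasmonate and ethylene defence genes, 1 of 8 rose and 0 fell (5 and 0), with ORA59, which joins both signals, at 1.15 ± 0.22. The list's median was 1.68 (adjusted p = 2.3e-06, and adjusted p = 0.195 with an estimated correlation). PR1 stood at 14.7 and 2.11 CPM in these libraries and did not pass the test. GSTU3, PCR1 and AT1G57630 also rose in nup50c, against the same WT libraries (2, 12 and 14 counts), so such repeated rises are not independent. The total of 312 genes became 143 without WT replicate 1, 82 without WT replicate 2, 70 without nup82 replicate 1 and 115 without nup82 replicate 2. It was 924 without the low-count filter, 555 with the DESeq2 Wald test and 626 in a fit of only the 2 genotypes. The salicylic acid count became 1 without WT replicate 1, 1 without WT replicate 2, 0 without nup82 replicate 1 and 2 without nup82 replicate 2, and the phosphate count 1 without WT replicate 1, 0 without WT replicate 2 and 0 without nup82 replicate 1.

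In nup136, most jasmonate and some salicylic acid genes rose, and most nitrate genes fell. Of jasmonate response genes, 14 of 19 rose and 0 fell (16 and 0 adjusted over the list alone): AOC1, LOX3 and OPR3, enzymes of jasmonate synthesis, rose by 3.05 ± 0.30, 2.60 ± 0.24 and 2.58 ± 0.18 on the log2 scale. For jasmonate response genes the median was 1.82, or 1.78 with genes at the floor set at their bounds (camera adjusted p = 1.95e-26, adjusted p = 0.102 with an estimated correlation). Of salicylic acid defence genes, 13 of 30 rose and 1 fell (17 and 4), with PR1 higher 92.2-fold (20.4 ± 7.64 against 0.207 ± 0.218 CPM, adjusted p = 0.0389), the glutaredoxin GRXC9 at 3.34 ± 0.47 and the transcription factor WRKY70 at -1.05 ± 0.21. The median of salicylic acid defence genes was 0.73 (adjusted p = 1.16e-05, and adjusted p = 0.244 with an estimated correlation). Of flavonoid and anthocyanin genes, 7 of 18 rose and 2 fell (8 and 3), with the transferase TT19 at 1.77 ± 0.22 and the enzyme DFR at 1.71 ± 0.12. Flavonoid and anthocyanin genes had a median of 0.64 (adjusted p = 0.0239, and adjusted p = 0.452 with an estimated correlation). Of nitrate response genes, 0 of 14 rose and 8 fell (0 and 9), with BT2 at -1.16 ± 0.09 and the nitrate reductase NIA1 at -0.66 ± 0.10. Nitrate response genes had a median of -0.39 (adjusted p = 1.92e-06, and adjusted p = 0.0898 with an estimated correlation). Of nuclear transport and mRNA export genes, 7 of 24 rose and 0 fell (7 and 0), with the GTPase RAN1 at 0.83 ± 0.08 and the exportin XPO1B at 0.64 ± 0.10. Nuclear transport and mRNA export genes had a median of 0.05 (adjusted p = 0.0202, and adjusted p = 0.390 with an estimated correlation). PR1 did not pass the test when any 1 of the 4 libraries was left out.

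Single genes changed far more in nup136. AT5G37140, annotated as a helicase gene, rose 646-fold (33.6 ± 0.893 against 0.0532 ± 0.0752 CPM, adjusted p = 4.81e-13), and AT5G37990, a methyltransferase gene, fell 589-fold (0.145 ± 0.0557 against 88.5 ± 4.70 CPM, adjusted p = 1.4e-07). NATA1, an acetyltransferase that acts on ornithine, rose at least 229-fold, AOX1D, an alternative oxidase of mitochondria, at least 33.3-fold and CSLG2, of the cellulose synthase-like family, at least 21.6-fold, each over a WT group with 0 counts. The cytochrome P450 gene CYP76G1 fell 14.5-fold, AT5G08250 11.1-fold, AT4G07820 10.2-fold and ZAT7, a zinc finger transcription factor, 9.97-fold. Of touch and wound genes, 1 of 12 rose and 5 fell (2 and 8 adjusted over the list alone), with ERF104 at -1.82 ± 0.40 and TCH4 at -1.40 ± 0.13. Touch and wound genes had a median of -0.60 (camera adjusted p = 2.65e-05, adjusted p = 0.370 with an estimated correlation). Of root markers 1 of 19 rose and 7 fell (1 and 9). Root markers had a median of -0.38 (adjusted p = 0.00106, and adjusted p = 0.370 with an estimated correlation). The total of 3228 genes in nup136 became 1806 without WT replicate 1, 1842 without WT replicate 2 and 1822 without nup136 replicate 2, the lower touch genes 3 without WT replicate 1 and 3 without nup136 replicate 1, and the lower root markers 3 without WT replicate 1, 4 without WT replicate 2 and 2 without nup136 replicate 2.

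In the libraries labelled nup50c nup82, a few genes of heat shock and jasmonate responses rose. HSFA2, a heat shock transcription factor, rose 5.32-fold (8.30 ± 0.668 against 1.55 ± 0.168 CPM, adjusted p = 0.000619), and of heat shock genes 6 of 21 rose and 0 fell (7 and 0 adjusted over the list alone), with HSP70-4 at a log2 fold change of 1.25 ± 0.23 and HSP101 at 1.02 ± 0.20. Heat shock genes had a median of 0.36 (camera adjusted p = 3.79e-08, adjusted p = 0.190 with an estimated correlation). Of jasmonate response genes, 6 of 19 rose and 0 fell (10 and 0), with AOC1 at 1.78 ± 0.29 and JAZ7 at 1.77 ± 0.30. The median of jasmonate response genes was 0.54 (adjusted p = 8.17e-13, and adjusted p = 0.195 with an estimated correlation). Of salicylic acid defence genes, 5 of 30 rose and 0 fell (11 and 1), with PNP-A, a secreted peptide gene, higher 4.85-fold, AED1 6.12-fold and PCR1 23.9-fold. The list's median was 0.53 (adjusted p = 2.67e-06, and adjusted p = 0.244 with an estimated correlation). AT5G24200 rose 7.93-fold (adjusted p = 0.0153). AT2G41980 fell 31.2-fold (adjusted p = 3.25e-13), XPL1 2.36-fold (adjusted p = 6.19e-10), AT1G13130 4.39-fold and AT4G18425 2.44-fold. The total of 203 genes became 83 without WT replicate 1, 70 without WT replicate 2, 51 without nup50c nup82 replicate 1 and 114 without nup50c nup82 replicate 2. It was 728 without the low-count filter, 489 with the DESeq2 Wald test and 317 in a fit of only the 2 genotypes. The heat shock count became 3 without WT replicate 1, 2 without WT replicate 2 and 2 without nup50c nup82 replicate 2, the jasmonate count 2 without WT replicate 2 and 1 without nup50c nup82 replicate 1, and the salicylic acid count 1 without WT replicate 1, 2 without WT replicate 2, 3 without nup50c nup82 replicate 1 and 3 without nup50c nup82 replicate 2.

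In nup50c nup136, some anthocyanin and nuclear transport genes rose, and most root and nitrate and some photosynthesis genes fell. Of flavonoid and anthocyanin genes, 9 of 18 rose and 2 fell (10 and 2 adjusted over the list alone), with the enzymes LDOX, DFR and TT19 at log2 fold changes of 2.66 ± 0.17, 2.52 ± 0.12 and 2.52 ± 0.22. For flavonoid and anthocyanin genes the median was 0.98 (camera adjusted p = 0.000772, adjusted p = 0.352 with an estimated correlation). Of nuclear transport and mRNA export genes, 11 of 24 rose and 1 fell (12 and 1), with RAN1 at 1.39 ± 0.08 and XPO1B at 1.35 ± 0.10. For nuclear transport and mRNA export genes the median was 0.24 (adjusted p = 5.8e-05, and adjusted p = 0.244 with an estimated correlation). Of root markers, 1 of 19 rose and 13 fell (1 and 14), with the root stem cell regulator PLT1 at -1.31 ± 0.25 and CASP1, of the Casparian strip, at -1.18 ± 0.13, while WOX5, a marker of the quiescent centre, rose by 1.39 ± 0.29. For root markers the median was -0.71 (adjusted p = 4.26e-06, and adjusted p = 0.251 with an estimated correlation). Of nitrate response genes, 1 of 14 rose and 9 fell (2 and 9), with NRT3.1 at -1.18 ± 0.14. For nitrate response genes the median was -0.50 (adjusted p = 4.45e-05, and adjusted p = 0.102 with an estimated correlation). Of photosynthesis genes 2 of 32 rose and 13 fell (2 and 14), with LHCB1.1 at -0.63 ± 0.07. Photosynthesis genes had a median of -0.16 (adjusted p = 0.000224, and adjusted p = 0.327 with an estimated correlation). Of jasmonate response genes, 7 of 19 rose and 0 fell (8 and 0). Jasmonate response genes had a median of 0.66 (adjusted p = 5.13e-05, and adjusted p = 0.370 with an estimated correlation).

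Among single genes of nup50c nup136, AT5G37140 rose 302-fold (adjusted p = 1.71e-12), AT1G10585 38.9-fold (adjusted p = 2.92e-09), NATA1 at least 96.4-fold, DXPS1, related to enzymes of plastid isoprenoid synthesis, at least 32.6-fold and CSLG2 at least 20.4-fold. CYP76G1 fell at least 49.3-fold, CYP93D1, another cytochrome P450 gene, 29.7-fold, the cineole synthase gene AT3G25820 23.7-fold, AT5G37990 23.2-fold and AT1G56060 17.2-fold. The total of 5550 genes became 3542 without WT replicate 1, 3647 without WT replicate 2 and 3386 without nup50c nup136 replicate 2, and the lower root markers 6 without nup50c nup136 replicate 2. The fall of AT3G25820 rested on WT replicate 1: the WT libraries held 13.4 and 1.09 CPM, and without that library its log2 fold change was -1.83 (adjusted p = 0.131). It did not pass without either nup50c nup136 library or in a fit of only the 2 genotypes (adjusted p from 0.0786 to 0.244).

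In the libraries labelled nup82 nup136, transcripts of seed storage were counted in the harvest of 9-day-old seedlings. Whether they came from the seedlings or from left-over seeds stays open. Of seed and embryo markers, 11 of 13 rose and 0 fell (12 and 0 adjusted over the list alone), with CRC, a cruciferin, higher 1125-fold (counting interval 311 to 9299), OLEO1, an oil body protein, 244-fold (counting interval 67.3 to 2023) and CRA1, another cruciferin, 62.8-fold (adjusted p = 0.0105). Seed and embryo markers had a median of 6.12, or 5.81 with genes at the floor set at their bounds (camera adjusted p = 2.67e-06, adjusted p = 0.244 with an estimated correlation). CRA1 stood at 20.7 and 45.6 CPM in the libraries against 0 and 1.12 in those of WT, so its fold rested on WT replicate 2. It did not pass with the DESeq2 Wald test (adjusted p = 0.124) or in a fit of only the 2 genotypes (adjusted p = 0.154). OLEO2 stood at 4.42 and 35.2. Of photosynthesis genes, 0 of 32 rose and 19 fell (1 and 22), with the antenna genes LHCB2.1 and LHCB1.1 at -0.70 ± 0.08 and -0.53 ± 0.07. For photosynthesis genes the median was -0.24 (adjusted p = 1.43e-09, and adjusted p = 0.195 with an estimated correlation). Of glucosinolate synthesis genes, 1 of 14 rose and 7 fell (1 and 10), with CYP79F1 at -1.81 ± 0.09 and BCAT4 at -1.32 ± 0.18. For glucosinolate synthesis genes the median was -0.35 (adjusted p = 4.25e-06, and adjusted p = 0.271 with an estimated correlation). Of sulfur deficiency genes 1 of 12 rose and 7 fell (1 and 7), with the sulfate reductase APR2 at -0.81 ± 0.15. Sulfur deficiency genes had a median of -0.58 (adjusted p = 0.00145, and adjusted p = 0.402 with an estimated correlation). The photosynthesis count became 12 without WT replicate 2 and the seed count 7 without WT replicate 1.

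Some root and iron genes also fell in the libraries labelled nup82 nup136. Of root markers, 1 of 19 rose and 9 fell (1 and 12 adjusted over the list alone), with the root hair gene EXPA7 at a log2 fold change of -1.27 ± 0.20. The median of root markers was -0.60 (camera adjusted p = 9.52e-06, adjusted p = 0.261 with an estimated correlation). Of iron deficiency genes, 0 of 18 rose and 6 fell (0 and 6), with the reductase FRO2 at -1.46 ± 0.51 and the regulator FIT at -0.91 ± 0.23. Iron deficiency genes had a median of -0.59 (adjusted p = 0.00352, and adjusted p = 0.423 with an estimated correlation). Of heat shock genes, 7 of 21 rose and 1 fell (7 and 1), with HSFA2 at 2.92 ± 0.33. For heat shock genes the median was 0.65 (adjusted p = 0.000134, and adjusted p = 0.244 with an estimated correlation). Of nuclear transport genes 9 of 24 rose and 0 fell (11 and 0). Nuclear transport genes had a median of 0.17 (adjusted p = 0.000154, and adjusted p = 0.244 with an estimated correlation). LCR67, a plant defensin, rose at least 45.6-fold over WT at 0 counts and AT5G37140 90.9-fold (adjusted p = 9.52e-10). CYP93D1 fell 117-fold (counting interval 31.9 to 970), AT2G22590, a glycosyltransferase gene, 37.0-fold, CYP76G1 27.0-fold, the defensin PDF1.2A 13.4-fold and the receptor-like kinase CRK4 10.3-fold. The total of 4325 genes became 2578 without WT replicate 1 and 2768 without WT replicate 2, the iron count 3 without WT replicate 2 and 3 without nup82 nup136 replicate 1, and the heat shock count 3 without WT replicate 1, 4 without WT replicate 2, 3 without nup82 nup136 replicate 1 and 4 without nup82 nup136 replicate 2.

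In the triple mutant against WT, most members of the photosynthesis, root, iron and sulfur lists fell. Of photosynthesis genes, 1 of 32 rose and 28 fell (1 and 28 adjusted over the list alone), with the antenna genes LHCB1.1 and LHCB2.3 at log2 fold changes of -1.66 ± 0.07 and -1.51 ± 0.09 and RBCS2B, a Rubisco small subunit, at -1.25 ± 0.08. The median of photosynthesis genes was -0.69 (camera adjusted p = 4.8e-17, adjusted p = 0.102 with an estimated correlation). Of root markers, 1 of 19 rose and 13 fell (1 and 15), with the root hair genes PRP3 and LRX1 at -2.01 ± 0.18 and -1.97 ± 0.20, and WOX5 at 1.31 ± 0.29. Root markers had a median of -1.45 (adjusted p = 1.65e-05, and adjusted p = 0.261 with an estimated correlation). Of iron deficiency genes, 1 of 18 rose and 11 fell (1 and 14): IRT1, the iron transporter of the root, had 0 counts and fell at least 48.8-fold from 3.54 ± 1.94 CPM (adjusted p = 0.00749), the regulator BHLH101 fell by 5.05 ± 0.90 on the log2 scale and the peptide gene IMA3 by 3.81 ± 0.81. For iron deficiency genes the median was -1.28 (adjusted p = 0.00580, and adjusted p = 0.427 with an estimated correlation). Of sulfur deficiency genes, 0 of 12 rose and 10 fell (0 and 10), with SDI1, a repressor of glucosinolate synthesis, at -1.64 ± 0.18 and SHM7 at -0.92 ± 0.11. For sulfur deficiency genes the median was -0.85 (adjusted p = 0.000224, and adjusted p = 0.370 with an estimated correlation). Of nitrate response genes, 3 of 14 rose and 8 fell (3 and 8), with the transporter NRT2.1 at -3.49 ± 0.89. The median of nitrate response genes was -0.27 (adjusted p = 0.246, and adjusted p = 0.402 with an estimated correlation). Of phosphate starvation genes 2 of 15 rose and 4 fell (2 and 4), with the ribonuclease RNS1 at 4.02 ± 0.36 and MGD3 at -2.04 ± 0.32. For phosphate starvation genes the median was -0.42 (adjusted p = 0.378, and adjusted p = 0.860 with an estimated correlation). The iron count became 6 without WT replicate 2.

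Most members of the camalexin and senescence lists rose in the triple mutant. Of pattern-triggered defence and camalexin genes, 8 of 12 rose and 1 fell (8 and 1 adjusted over the list alone), with CYP71A13, an enzyme of camalexin synthesis, at a log2 fold change of 6.65 ± 2.07, the receptor kinase FRK1 at 1.91 ± 0.42, and WRKY33, a regulator of that pathway, at -0.76 ± 0.19. Pattern-triggered defence and camalexin genes had a median of 1.08 (camera adjusted p = 0.00710, adjusted p = 0.244 with an estimated correlation). Of senescence and dark genes, 7 of 12 rose and 2 fell (7 and 2), with SAG13 at 7.44 ± 0.91 and the regulator ORE1 at 1.98 ± 0.28. Senescence and dark genes had a median of 0.67 (adjusted p = 0.00814, and adjusted p = 0.261 with an estimated correlation). Of seed and embryo markers, 9 of 13 rose and 0 fell (11 and 0). For seed and embryo markers the median was 5.29, or 4.39 with genes at the floor set at their bounds (adjusted p = 0.0239, and adjusted p = 0.426 with an estimated correlation). CRC stood at 6.94 and 4.57 CPM in the libraries and CRA1 at 23.0 and 18.4. Of heat shock genes, 9 of 21 rose and 2 fell (9 and 2), with HSP23.6 at 2.86 ± 1.08. The median of heat shock genes was 0.86 (adjusted p = 0.0349, and adjusted p = 0.426 with an estimated correlation). Of flavonoid and anthocyanin genes, 8 of 18 rose and 2 fell (9 and 2), with LDOX at 2.36 ± 0.17 and the flavonol synthase FLS1 at -1.48 ± 0.09. The median of flavonoid and anthocyanin genes was 0.69 (adjusted p = 0.0424, and adjusted p = 0.519 with an estimated correlation). Of DNA damage response genes, 6 of 13 rose and 1 fell (6 and 1), with GMI1 at 2.21 ± 0.16 and the cell cycle inhibitor SMR7 at 2.04 ± 0.49. DNA damage response genes had a median of 0.39 (adjusted p = 0.0434, and adjusted p = 0.370 with an estimated correlation). Of unfolded protein response genes, 4 of 10 rose and 0 fell (4 and 0). Unfolded protein response genes had a median of 0.25 (adjusted p = 0.0514, and adjusted p = 0.426 with an estimated correlation). CYP71A13 did not pass the test when any 1 of the 4 libraries was left out (adjusted p from 0.0546 to 0.133), and HSP23.6 did not when any of them but WT replicate 2 was left out.

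Some genes of the transport machinery itself rose in the triple mutant. Of nuclear transport and mRNA export genes, 13 of 24 rose and 1 fell (14 and 1 adjusted over the list alone), with RAN1 and RAN2 at log2 fold changes of 2.03 ± 0.08 and 1.55 ± 0.08, the exportin XPO1B at 1.56 ± 0.10, the export factor UAP56B at 1.01 ± 0.07 and SAC3B, of the export complex at the basket, at -0.51 ± 0.10. The list's median was 0.32 (camera adjusted p = 0.000145, adjusted p = 0.244 with an estimated correlation). Of nuclear pore and lamina genes, 10 of 36 rose and 6 fell (10 and 6), with NUP98B at 2.70 ± 0.14, RAE1 at 1.66 ± 0.09, the ring protein gene NDC1 at 1.01 ± 0.12 and the lamina gene CRWN1 at -0.57 ± 0.08. This list's median was 0.06 (adjusted p = 0.624, and adjusted p = 0.900 with an estimated correlation).

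Several hormone and stress lists of the triple mutant went both ways. Of salicylic acid defence genes, 10 of 30 rose and 7 fell (11 and 7 adjusted over the list alone), with PR1 at 7.40 ± 1.69 and ACD6 at -1.80 ± 0.26. For salicylic acid defence genes the median was 0.04 (camera adjusted p = 0.490, adjusted p = 0.856 with an estimated correlation). Of jasmonate response genes, 6 of 19 rose and 4 fell (6 and 4), with JAZ8 at 2.27 ± 0.67 and VSP1 at -1.62 ± 0.38. For jasmonate response genes the median was 0.19 (adjusted p = 0.145, and adjusted p = 0.765 with an estimated correlation). Of jasmonate and ethylene defence genes, 3 of 8 rose and 3 fell (4 and 3), with ERF1 at 3.83 ± 1.00 and PDF1.2A lower at least 23.3-fold. That list's median was -0.83, or -0.81 with genes at the floor set at their bounds and its mean -1.90, whereas camera ranked it upward (adjusted p = 0.544, and adjusted p = 0.856 with an estimated correlation). Of auxin response genes, 4 of 30 rose and 10 fell (4 and 10), with IAA6 at -3.03 ± 0.59 and SAUR22 at -2.09 ± 0.75. Auxin response genes had a median of -0.28 (adjusted p = 0.164, and adjusted p = 0.402 with an estimated correlation). Of abscisic acid, cold and drought genes, 11 of 28 rose and 11 fell (11 and 11), and median 0.02 and mean 0.31 differed in sign from the downward rank (adjusted p = 0.927, and adjusted p = 0.970 with an estimated correlation). The lower salicylic acid genes became 4 without WT replicate 2 and 4 without nup50c nup82 nup136 replicate 1, the lower jasmonate genes 2 without nup50c nup82 nup136 replicate 2, the lower jasmonate and ethylene genes 1 without WT replicate 1, 1 without nup50c nup82 nup136 replicate 1 and 1 without nup50c nup82 nup136 replicate 2, and the higher auxin genes 2 without nup50c nup82 nup136 replicate 1. SAUR22 did not pass the test without WT replicate 2 (log2 fold change -0.74, adjusted p = 0.546) or without nup50c nup82 nup136 replicate 2 (adjusted p = 0.192).

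Single genes changed more strongly, and DXPS1 stood at 10.0 ± 2.15 CPM in the triple mutant over 0 counts in WT (adjusted p = 0.00589). LCR67 rose at least 239-fold (17.5 ± 0.781 CPM over WT at 0 counts, adjusted p = 0.00118), NATA1 at least 198-fold, CSLG2 at least 129-fold and AOX1D at least 94.1-fold. AT5G37140 rose 465-fold (24.2 ± 0.429 against 0.0532 ± 0.0752 CPM), CRC 234-fold (counting interval 64.5 to 1940), GSTU3 215-fold (counting interval 59.1 to 1778), AT1G10585 208-fold (21.1 ± 2.05 against 0.102 ± 0.0808 CPM) and ELI3-2, an alcohol dehydrogenase of defence, 204-fold (25.3 ± 0.119 against 0.113 ± 0.160 CPM). CYP93D1 fell at least 39.0-fold, AGL19, a MADS-box promoter of flowering, 53.5-fold (adjusted p = 2.08e-08), AT2G15042, a leucine-rich repeat protein gene, 51.8-fold, CWINV5, a cell wall invertase, 48.4-fold, CYP76G1 44.5-fold, the thionin gene AT1G66100 40.7-fold and AT2G22590 25.0-fold. PCR1, higher in nup50c and in the libraries labelled nup82, fell at least 2.08-fold from 0.156 ± 0.156 CPM (adjusted p = 0.0470). Fitted log2 values of genes with 3 or fewer counts in a genotype are no bound, so for comparisons of 2 genotypes ratios of counts stand in their place. Families such as LHCB1, RBCS, PDF1.2, SAUR, VSP and HSP hold near-identical copies, so the counts of their single members are uncertain. The strand setting was not given, so overlapping genes on opposite strands are not separable.

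The remaining lists of the triple mutant gave smaller or mixed shifts. Of flowering time genes, 3 of 24 rose and 10 fell (3 and 10 adjusted over the list alone), with FD at -2.63 ± 0.35 and CO at 1.62 ± 0.48. Flowering time genes had a median of -0.39 (camera adjusted p = 0.126, adjusted p = 0.327 with an estimated correlation). Of circadian clock genes, 1 of 18 rose and 10 fell (2 and 10), with CHE at -1.22 ± 0.08 and PRR9 at 1.16 ± 0.36. Circadian clock genes had a median of -0.32 (adjusted p = 0.0675, and adjusted p = 0.270 with an estimated correlation). Of glucosinolate synthesis genes, 5 of 14 rose and 7 fell (5 and 7), with CYP79F1 at -2.42 ± 0.10 and CYP79B2 at 1.34 ± 0.18. The median of glucosinolate synthesis genes was -0.21 (adjusted p = 0.304, and adjusted p = 0.850 with an estimated correlation). Of cell division genes, 4 of 23 rose and 4 fell (1 and 4). Cell division genes had a median of -0.09 (adjusted p = 0.462, and adjusted p = 0.856 with an estimated correlation). Of DNA methylation and silencing genes, 2 of 9 rose and 6 fell (2 and 6), with FWA, silenced by methylation in WT plants, higher at least 12.2-fold and the demethylase ROS1 at -1.06 ± 0.12. That list's median was -0.43 and its mean 0.22, with a downward rank (adjusted p = 0.164, and adjusted p = 0.452 with an estimated correlation). Of touch and wound genes, 5 of 12 rose and 3 fell (5 and 3), with MYB15 at 4.02 ± 0.31 and TCH4 at -2.35 ± 0.13. For touch and wound genes the median was 0.26 (adjusted p = 0.730, and adjusted p = 0.925 with an estimated correlation). Of shoot meristem, stomatal lineage and trichome markers, 0 of 11 rose and 5 fell (0 and 5), with the trichome regulator GL1 at -2.25 ± 0.44. Shoot meristem, stomatal lineage and trichome markers had a median of -0.50 (adjusted p = 0.182, and adjusted p = 0.370 with an estimated correlation). BCP1, a pollen marker, rose 23.5-fold (counting interval 6.17 to 200), and the pollen list had too few tested members for a test. The lower clock genes became 6 without nup50c nup82 nup136 replicate 2, the higher cell division genes 1 without WT replicate 1, 2 without WT replicate 2, 1 without nup50c nup82 nup136 replicate 1 and 2 without nup50c nup82 nup136 replicate 2, and the higher touch genes 3 without WT replicate 1 and 3 without nup50c nup82 nup136 replicate 2.

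**Figure D3:**
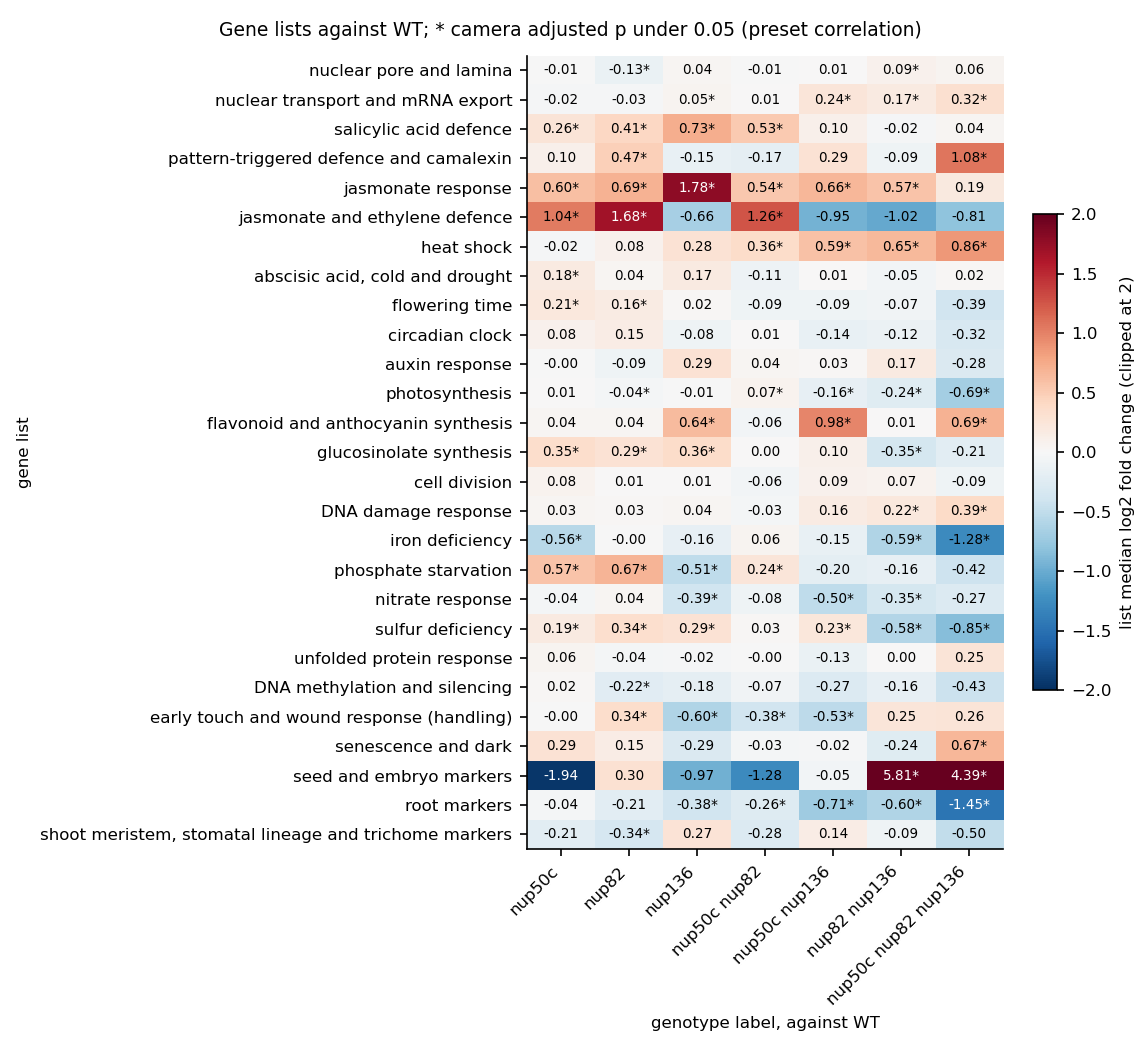
Median log2 fold change against WT of each fixed gene list (vertical) in each genotype (horizontal), with genes at 0 counts set at their bounds, and stars for camera at a preset correlation. The photosynthesis median was -0.24 in the libraries labelled nup82 nup136 and -0.69 in the triple mutant, and no starred call against WT held with an estimated correlation.

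**Figure D4:**
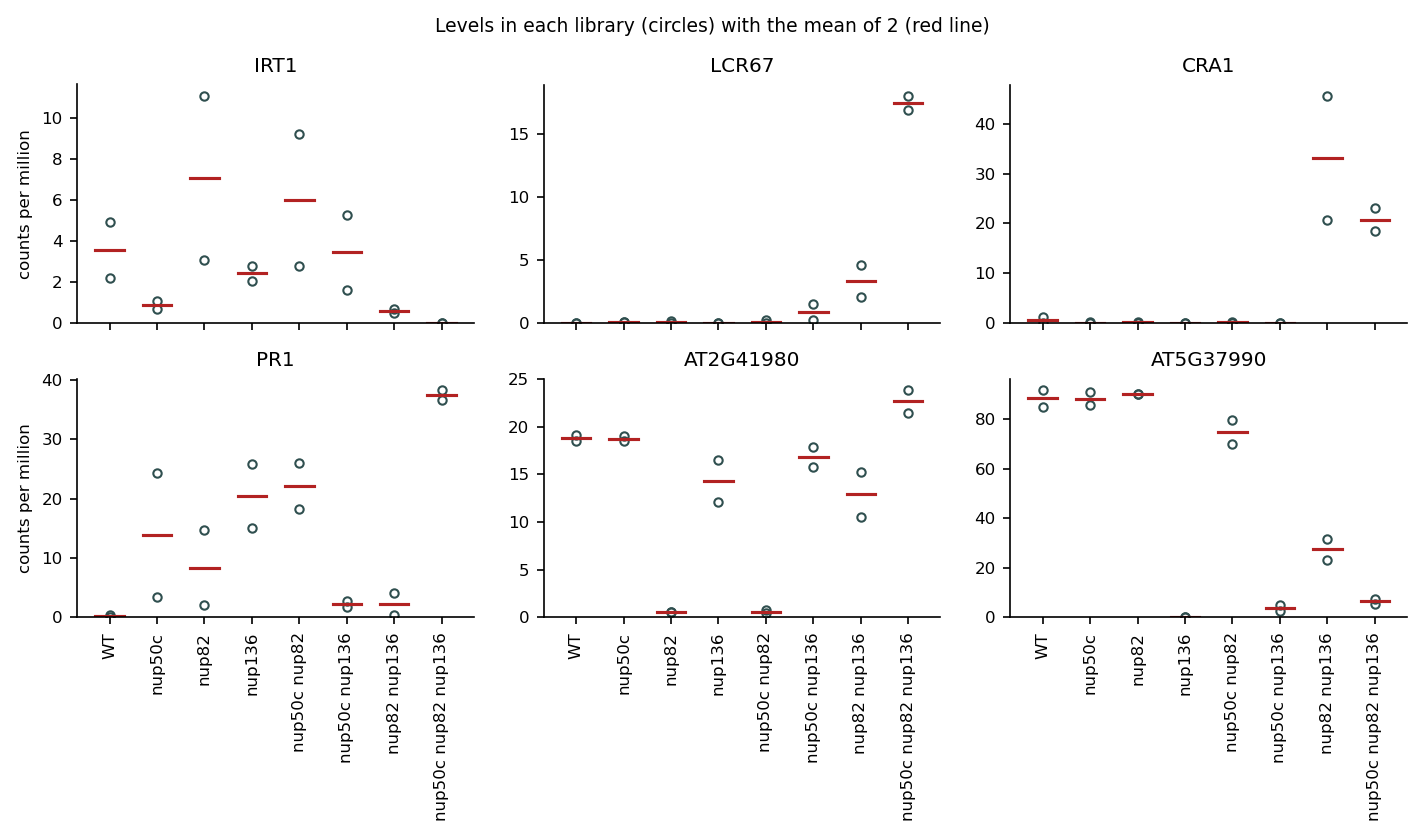
CPM (vertical axes, each with its own scale) of 6 genes in the 16 libraries, by genotype, with circles for libraries and lines for the mean of 2. IRT1 had 0 counts in both libraries of the triple mutant, and AT2G41980 stood at 21.4 and 23.8 there against 0.504 and 0.527 in the libraries labelled nup82.

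The effect of nup50c on the libraries labelled nup82 nup136 was read from the triple mutant against that genotype, with 3347 genes higher and 3331 lower. This even split became 2928 and 3810 with library totals as the only scaling, and fewer were higher than lower with DESeq2 size factors (3326 and 3370), with the DESeq2 Wald test (3423 and 3518), without the low-count filter (3506 and 3557), without nup82 nup136 replicate 1 (2469 and 2557) and without nup50c nup82 nup136 replicate 2 (2240 and 2243). Most members of the camalexin and senescence lists rose. Of pattern-triggered defence and camalexin genes, 7 of 12 rose and 0 fell (8 and 0 adjusted over the list alone), with PAD3 at a log2 fold change of 2.71 ± 0.51 and the receptor kinase FRK1 at 1.77 ± 0.41. The median was 1.18 (camera adjusted p = 4.05e-05, adjusted p = 0.0413 with an estimated correlation). Of senescence and dark genes, 9 of 12 rose and 0 fell (9 and 0), with SAG13 higher 40.1-fold (169 ± 10.8 against 4.21 ± 1.70 CPM, adjusted p = 0.000946) and ORE1 at 2.22 ± 0.29. This list's median was 0.99 (adjusted p = 8.46e-06, and adjusted p = 0.0457 with an estimated correlation). Of photosynthesis genes, 0 of 32 rose and 25 fell (0 and 26), with LHCB1.1 at -1.13 ± 0.07. The list's median was -0.43 (adjusted p = 1.14e-17, and adjusted p = 0.0413 with an estimated correlation). Of auxin response genes, 0 of 30 rose and 14 fell (0 and 15), with IAA6 at -2.56 ± 0.59 and SAUR20, of the growth-linked SAUR family, at -2.03 ± 0.45. The median was -0.68 (adjusted p = 7.94e-05, and adjusted p = 0.0457 with an estimated correlation). AOX1D rose 293-fold (counting interval 80.7 to 2425), AT5G39520 58.7-fold, AT1G10585 31.8-fold and NATA1 30.8-fold. AT1G66100 fell 12.5-fold, CWINV5 12.3-fold, AT5G46871 9.85-fold, AT2G15042 8.88-fold and PGL5, a phosphogluconolactonase, 8.11-fold.

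The effect of the nup82 label on nup50c nup136 gave 2261 higher and 2663 lower genes. Most seed markers rose here too: of seed and embryo markers 8 of 13 rose and 0 fell (11 and 0 adjusted over the list alone), with CRA1 higher at least 308-fold (20.7 ± 3.27 CPM against 0 counts, adjusted p = 0.00606), CRC 256-fold (counting interval 70.6 to 2124), the globulin gene AT2G28490 231-fold (counting interval 63.6 to 1915), the glucosidase BGLU19 157-fold (counting interval 53.2 to 762) and PER1, a peroxiredoxin of seeds, 56.0-fold. The median was 5.80, or 3.15 with genes at the floor set at their bounds (camera adjusted p = 0.000575, adjusted p = 0.206 with an estimated correlation). Of sulfur deficiency genes, 0 of 12 rose and 11 fell (0 and 11), with SDI1 at -2.58 ± 0.17. This list's median was -1.22 (adjusted p = 1.05e-11, and adjusted p = 0.0803 with an estimated correlation). Of iron deficiency genes 0 of 18 rose and 11 fell (1 and 12), with IRT1 lower at least 47.9-fold. The list's median was -1.51 (adjusted p = 0.000575, and adjusted p = 0.233 with an estimated correlation). Root markers were lower as well, with library medians of -0.53 and -0.94 in nup50c nup136 and -1.12 and -1.37 in the triple mutant, as log2 ratios to the WT mean. Of photosynthesis genes, 0 of 32 rose and 29 fell (1 and 29), with LHCB2.3 at -1.48 ± 0.09. For photosynthesis genes the median was -0.50 (adjusted p = 9.54e-26, and adjusted p = 0.0247 with an estimated correlation). Of pattern-triggered defence genes, 9 of 12 rose and 0 fell (9 and 0), with PAD3 at 2.44 ± 0.50 and the transcription factor WRKY40 at 1.79 ± 0.50 (adjusted p = 2.63e-08, and adjusted p = 0.0247 with an estimated correlation). The touch and wound list, a check of handling at harvest, differed here too. Its library medians, as log2 ratios to the WT mean, were -0.67 and -0.44 in nup50c nup136 and 0.22 and 0.31 in the triple mutant. A role of handling was not tested. Of unfolded protein response genes, 7 of 10 rose and 0 fell (7 and 0). For unfolded protein response genes the median was 0.36 (adjusted p = 2.87e-05, and adjusted p = 0.116 with an estimated correlation). CWINV5 fell 27.7-fold, AT1G66100 11.0-fold, AT1G14250, an apyrase gene, 10.6-fold and CYP93D1 at least 1.27-fold. PER1 passed the test only without nup50c nup136 replicate 1 of the 4 libraries left out in turn, and neither with the DESeq2 Wald test (adjusted p = 0.303) nor with a replicate block (adjusted p = 0.0591). The total of 4924 genes became 3130 without nup50c nup82 nup136 replicate 1 and 3110 without nup50c nup82 nup136 replicate 2. The direction rests on labels that NUP82 transcript levels do not show.

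The effect of nup136 on the libraries labelled nup50c nup82 was the largest of the 3, with 4991 genes higher and 5383 lower, or 5714 and 5508 in a fit of only the 2 genotypes compared, where the larger direction turned. Of photosynthesis genes, 0 of 32 rose and 29 fell (1 and 29 adjusted over the list alone), with LHCB1.1 at a log2 fold change of -1.81 ± 0.07. The median of photosynthesis genes was -0.79 (camera adjusted p = 3.9e-19, adjusted p = 0.0413 with an estimated correlation). Of nuclear transport and mRNA export genes, 15 of 24 rose and 2 fell (15 and 2). The list's median was 0.41 (adjusted p = 3.32e-05, and adjusted p = 0.129 with an estimated correlation). Of pattern-triggered defence genes 7 of 12 rose and 0 fell (7 and 0). Pattern-triggered defence genes had a median of 1.27 (adjusted p = 0.00132, and adjusted p = 0.0803 with an estimated correlation). Of seed and embryo markers 11 of 13 rose and 0 fell (11 and 0). Seed and embryo markers had a median of 5.94, or 4.69 with genes at the floor set at their bounds (adjusted p = 0.0112, and adjusted p = 0.311 with an estimated correlation). Of root markers, 0 of 19 rose and 12 fell (0 and 14). For root markers the median was -0.91 (adjusted p = 0.000254, and adjusted p = 0.210 with an estimated correlation). PER1 rose at least 161-fold, M17, of the late embryogenesis proteins, at least 79.8-fold, CRC at least 75.9-fold, the protease gene AT3G54940 at least 45.9-fold and AT5G37140 961-fold (counting interval 266 to 7941). IRT1 fell at least 82.8-fold, the defensins PDF1.2A at least 80.0-fold and PDF1.2C 140-fold (counting interval 38.5 to 1165), PCR1 at least 51.1-fold and CYP93D1 at least 24.5-fold. Of the 81 list tests in the 3 third-mutation comparisons, 7 held with an estimated correlation. These were not repeated without 1 library. Photosynthesis held in each, and pattern-triggered defence against nup50c nup136 and the libraries labelled nup82 nup136. Auxin response and senescence held against the latter only.

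Non-additivity compares each multiple mutant with the sum of its single effects on the log2 scale. Of jasmonate genes, most of which rose in nup136, some lay below that sum in 2 of the combinations. All terms use the same WT libraries, so they are not independent of one another. Those that involve nup82 rest on its labels. For nup82 with nup136, of jasmonate response genes 0 of 19 rose and 12 fell (1 and 17 adjusted over the list alone). The median of jasmonate response genes was -2.35 (camera adjusted p = 7.17e-21, adjusted p = 0.0772 with an estimated correlation). Of salicylic acid defence genes 0 of 30 rose and 14 fell (0 and 20). The median of salicylic acid defence genes was -1.14 (adjusted p = 3.39e-12, and adjusted p = 0.0772 with an estimated correlation). Of glucosinolate synthesis genes 0 of 14 rose and 12 fell (0 and 12). Glucosinolate synthesis genes had a median of -1.25 (adjusted p = 7.17e-21, and adjusted p = 0.0772 with an estimated correlation). For nup50c with nup136, of jasmonate response genes 0 of 19 rose and 9 fell (0 and 13). Jasmonate response genes had a median of -1.66 (adjusted p = 1.14e-20, and adjusted p = 0.0772 with an estimated correlation). Of glucosinolate synthesis genes 0 of 14 rose and 10 fell (0 and 12). For glucosinolate synthesis genes the median was -0.78 (adjusted p = 1.65e-17, and adjusted p = 0.0772 with an estimated correlation). For nup50c with nup82, of glucosinolate synthesis genes 0 of 14 rose and 7 fell (0 and 9). The median of glucosinolate synthesis genes was -0.60 (adjusted p = 1.4e-11, and adjusted p = 0.109 with an estimated correlation). In the three-way term, of salicylic acid defence genes 10 of 30 rose and 1 fell (15 and 1). Salicylic acid defence genes had a median of 1.42 (adjusted p = 8.15e-08, and adjusted p = 0.104 with an estimated correlation). Of pattern-triggered defence genes 6 of 12 rose and 0 fell (7 and 0). For pattern-triggered defence genes the median was 1.92 (adjusted p = 1.82e-06, and adjusted p = 0.0772 with an estimated correlation). Of photosynthesis genes 2 of 32 rose and 14 fell (2 and 20). Photosynthesis genes had a median of -0.44 (adjusted p = 2.96e-11, and adjusted p = 0.104 with an estimated correlation).

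In all, 517 genes were higher and 556 lower than additive for nup50c with nup82, 550 and 609 for nup50c with nup136, 772 and 1195 for nup82 with nup136, and 1141 and 1000 in the three-way term. Without the low-count filter, 1742 genes departed for nup50c with nup82 and 1769 for nup50c with nup136. The total of 1073 for nup50c with nup82 became 657 without WT replicate 2, 515 without nup50c replicate 2, 625 without nup82 replicate 1, 690 without nup82 replicate 2 and 695 without nup50c nup82 replicate 1. The total of 1159 for nup50c with nup136 became 728 without WT replicate 2, and that of 1967 for nup82 with nup136 1216 without WT replicate 2 and 1210 without nup82 replicate 1. More genes were higher than lower for nup50c with nup82 without WT replicate 2 (336 and 321), without nup50c replicate 2 (258 and 257) and without nup50c nup82 replicate 1 (350 and 345), and for nup50c with nup136 without WT replicate 2 (384 and 344).

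Each mutation was also followed through the 4 genetic backgrounds it was placed in, with no library shared between the effects compared. The nup50c label went with 389 genes in WT, 762 in the libraries labelled nup82, 1995 in nup136 and 6678 in the libraries labelled nup82 nup136. The nup82 label went with 312, 987, 2829 and 4924 genes in WT, nup50c, nup136 and nup50c nup136, and nup136 with 3228, 6050, 4822 and 10374 in WT, nup50c, the libraries labelled nup82 and those labelled nup50c nup82. Across all genes, which are not independent replicates, the median Pearson r between the effects of 1 mutation in different backgrounds was 0.0176 for nup50c, 0.0105 for nup82 and 0.375 for nup136, over 6 pairs each. The median turned negative for nup50c without nup50c nup82 replicate 1 (-0.0055) and for nup82 without nup50c nup82 replicate 2 (-0.0055). The lowest r within each was -0.0933, -0.134 and 0.122, and the largest 0.232, 0.367 and 0.542. Over genes with a mean of at least 10 CPM the medians were -0.0305, 0.0294 and 0.571, with the sign reversed for nup50c, and over genes changed in any comparison with WT 0.0501, 0.0521 and 0.487. For each mutation, the pairs of backgrounds with the lowest and the highest share of genes changed in the same direction, of the 6, are given, with the numbers for independent calls in brackets, and no difference between pairs was tested. Of genes changed by nup50c both in WT and with nup82, 5 rose in both (3.06), 1 fell in both (3.498) and 120 were opposite. Of those changed both with nup136 and with nup82 nup136, 626 rose (146), 538 fell (151) and 107 were opposite. For the nup82 label the numbers were 14 (4.61), 5 (2.40) and 86 for WT with nup50c, and 378 (124), 793 (190) and 171 for nup136 with nup50c nup136. For nup136 they were 787 (327), 1159 (422) and 376 for WT with nup50c nup82, and 995 (257), 1614 (398) and 79 for nup50c with nup82.

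Of 95 tested genes of the plastid genome, 1 rose and 22 fell in the triple mutant against WT, at a median log2 fold change of -0.55, and 0 rose and 23 fell against the libraries labelled nup82 nup136, at a median of -0.62. That reference itself lay above WT, with 6 plastid genes higher and 1 lower in the libraries labelled nup82 nup136, at a median of 0.12. Of all 22427 tested genes, 5229 rose and 5445 fell in the triple mutant against WT, and the plastid genes were not tested as a set. Of 36 tested genes of the mitochondrial genome, 2 rose and 2 fell against WT. Libraries of mRNA hold transcripts of organelle genomes to an unknown extent, and these took between 0.0436% and 0.0729% of the counts.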

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

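All tests of explanations in this part were chosen only after the results they measure were seen, whereas the tests of non-additivity were planned.

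The multiple mutants departed from the sum of their parts in many genes, by a test of the difference itself: 1073 genes for nup50c with nup82, 1159 for nup50c with nup136, 1967 for nup82 with nup136 and 2141 in the three-way term. All these terms share the WT libraries, which enter the pairwise and the three-way terms with opposite signs. A low WT level alone would lower the former and raise the latter, which was not tested apart. PR1 and GSTU3, below, carry such signs. The terms with nup82 also assume like lines. AT2G41980 stood at 0.504 and 0.527 CPM in the libraries labelled nup82 and at 10.5 and 15.3 in those labelled nup82 nup136. A difference between lines stays open for these terms. The genes below carry log2 departures, which are fitted values. Those of GSTU3, CYP76G1, CRA1, BGLU19, M17, AOX1D and CSLG2 involve a genotype with 3 or fewer counts, so they depend on the prior count, are no bound and do not rank these genes.

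For nup50c with nup82, departures upward were NAS2 2.84, AT2G14247 2.80, HSFA2 2.58, the cell wall enzyme gene XTH25 2.57 and AT5G51440 2.47. Departures downward were GSTU3 -6.24, ORA47 -4.58, PCR1 -4.41, AT1G10585 -3.65 and AT1G57630 -3.53. For nup50c with nup136, they were RLP21 4.68, AT5G37990 4.66, AT2G14247 4.63, AT2G17850 4.37 and PDF1.4 3.90 upward, and PCR1 -10.44, PR1 -9.19, GSTU3 -8.05, TPS04 -7.14 and CYP76G1 -6.23 downward. For nup82 with nup136, they were CRA1 15.86, BGLU19 13.84, M17 11.98, AT5G37990 7.49 and LEA18 7.21 upward, and AOX1D -14.69, CYP71A13 -10.99, PCR1 -10.15, PR1 -8.40 and the terpene synthase TPS04 -8.15 downward. In the three-way term, they were AOX1D 18.90, CYP71A13 14.18, GSTU3 13.16, PR1 11.82 and CSLG2 11.09 upward, and AT5G37990 -6.47, NAS2 -4.37, AT1G15330 -4.14, HSFA2 -4.02 and AT1G18020 -3.41 downward. AT5G37990 stood at unequal levels in the genotypes with nup136, and a difference between lines at this gene was not tested.

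NUP82 transcript did not pass the test as lower than WT in the libraries labelled nup82 nup136 (85.3% of WT, adjusted p = 0.15) or nup50c nup82 nup136. These libraries did not match the genotype without nup82: the first differed from nup136 in 2829 genes and the second from nup50c nup136 in 4924. Between the libraries labelled nup50c nup82 and WT, 203 genes differed, which is no null value. This argues only against an exchange for samples like those of nup136 or nup50c nup136. A line that lacks nup82 and differs otherwise could give such numbers too, so the presence of nup82 stays open. AT2G41980, near 0 in the libraries labelled nup82 and nup50c nup82, is excluded as a marker shared by all 4 genotypes, since the lower of the libraries labelled nup50c nup82 nup136 stood at 114% of WT. Transcripts of a disrupted NUP82 allele, at 115% of WT in that genotype, may be counted over the whole gene, and counts without read positions leave this open. A nup82 allele that differs between lines was not tested either.

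Of 13 seed markers 11 rose in the libraries labelled nup82 nup136 (7 without WT replicate 1) and 9 in the triple mutant, and neither list call held with an estimated correlation (adjusted p = 0.244 and 0.426). Left-over seeds in the harvest stay open. The log2 differences of the 10 markers with over 3 counts in all 4 libraries were unequal between these genotypes (Cochran Q 34.4 against a chi-square with 9 degrees of freedom, p = 7.56e-05) and spanned 4.68. Over the same 10 markers the differences between the 2 libraries labelled nup82 nup136 spanned 4.67, with ABI3 at 42 and 48 counts and EM1 at 6 and 174, so the 2 spans were about equal and do not decide. Stray seed in single libraries stays open too. The lowest list median of these 4 libraries lay 1.096 on the log2 scale above the highest of the other 12, which restates the pattern. A joint effect of both mutations may be a candidate explanation, but only 2 of 13 markers passed the test of non-additivity, which decides nothing. Left-over seeds, seeds or embryos that differ between genotypes, and delayed loss of seed transcripts, cannot be told apart with these counts.

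Of root markers 13 of 19 fell and 1 rose in the triple mutant, and of iron deficiency genes 11 of 18 fell and 1 rose, or 6 fell without WT replicate 2. Neither list call held with an estimated correlation (adjusted p = 0.261 and 0.427). An equal fall of all root markers is argued against, since these moved unequally, from -2.01 to 1.31 (Cochran Q 242 against a chi-square with 18 degrees of freedom, p = 3.8e-41). This span of 3.33 exceeded those of 1.79 and 1.57 between the libraries of WT and of the triple mutant by over 1.5 times, a margin set after the spans were seen. A lower share of root as the whole cause stays open for the root markers. A changed mix of root cell types, or marker transcripts outside the root, would move them unequally too. For the iron genes a lower share of root stays open as well: their median was -1.28 against -1.45 for root markers (permutation p = 0.681, two-sided, 100000 resamples). A changed response to iron, which the genotype may bring, was not tested apart from this.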

How the results depend on the processing

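Library totals as the only scaling was chosen after the data were seen, and all other settings before. Single genes, named or on a list, were compared under the settings that follow and a replicate block, not without the low-count filter, and none reversed: of 909 values 20 lost their call with the DESeq2 Wald test, 2 of 910 with DESeq2 size factors, 14 of 910 with library totals, 59 of 859 in a fit of only the 2 genotypes compared, and 977 of 3880 without 1 library, while 1 gained it. Nearly all of these values were picked for their calls in these data, so reversals and gained calls were unlikely from the start. The numbers of changed genes stayed within 1.5 times in all 14 comparisons with DESeq2 size factors and library totals. Library totals shifted the median of all genes by at most 0.0545 on the log2 scale.

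A replicate block left all 14 numbers within 1.5 times and ended the call of 31 of 910 single values. Over the 28 pairs of genotypes, the correlation of the replicate differences lay between -0.0574 and 0.0468, so the numbers do not pair the libraries, and no block was used in the values reported.

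Without the filter on low counts, the numbers were 855 for nup50c, 924 for nup82 and 728 for nup50c nup82 against WT, 1742 for nup50c with nup82 and 1769 for nup50c with nup136. The DESeq2 Wald test gave 555 for nup82 and 489 for nup50c nup82 (254 higher, 51.9%, against 62.1% as reported), and a fit of only the 2 genotypes 626 and 317. The cause was not tested for any of these. An absolute log2 fold change of at least 1, which by its construction leaves fewer genes, gave 48 for nup50c, 45 for nup82, 521 for nup136, 46 for nup50c nup82, 1213 for nup50c nup136, 1059 for nup82 nup136 and 3313 for the triple mutant. It gave 1301, 1087 and 3043 for the triple mutant against nup82 nup136, nup50c nup136 and nup50c nup82, and 285, 392, 617 and 1002 for the 4 terms of non-additivity. Of the 189 list tests against WT, 72 passed as reported, 65 with fry, 73 with a replicate block and 0 with an estimated correlation, which by its construction widens the error of lists whose genes move together.

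Leaving out 1 library assumes that the lone sample of that genotype varies like the others. It also loosens the low-count filter, which then asks for enough counts in 1 library rather than 2. The numbers then ranged from 95 to 261 for nup50c, 70 to 143 for nup82, 1806 to 2817 for nup136, 51 to 114 for nup50c nup82, 3386 to 4422 for nup50c nup136 and 2578 to 3417 for nup82 nup136. They ranged from 8330 to 8654 for the triple mutant, 4478 to 5854 against nup82 nup136, 3110 to 3583 against nup50c nup136, 8153 to 8481 against nup50c nup82, 515 to 966 for nup50c with nup82, 728 to 1023 for nup50c with nup136, 1210 to 2392 for nup82 with nup136 and 1521 to 2707 in the three-way term. The 2392 and 2707, above the 1967 and 2141 reported, came without nup82 nup136 replicate 2. Fewer libraries by construction lower the power, which does not give a higher number. The filter was looser in these fits, so other genes were tested. The libraries labelled nup82 nup136 also had the largest spread of any pair (17.5 times counting alone), and leaving 1 out removes it from the estimate. Both also held without nup82 nup136 replicate 1, where fewer genes than reported departed, so the cause stays open.

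The nup50c effect across backgrounds had a median r of -0.0305 at a mean of at least 10 CPM, with the sign reversed, and 0.0501 over genes changed in any comparison with WT. The nup82 effect had 0.0294 and 0.0521, and the nup136 effect 0.5714 and 0.4873. Without 1 library the medians ranged from -0.0055 to 0.0299, -0.0055 to 0.0306 and 0.2809 to 0.3253. Those for nup136 all lay below the 0.375 reported, and the filter was looser in these fits. The cause was not tested. With 2 libraries per genotype, a simulated 1.5-fold departure from additivity was called in 13.4% of the changed genes, which limits what the three-way term can show. These were drawn from genes above a minimum mean level.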

Other observations

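Single genes of the pore rose in genotypes with nup136, while of all 36 nuclear pore and lamina genes 10 rose and 6 fell in the triple mutant (median 0.06, camera adjusted p = 0.624). NUP98B, a nucleoporin of the central channel, rose on the log2 scale by 0.99 ± 0.14 in nup136, 1.84 ± 0.14 in nup50c nup136, 1.82 ± 0.14 in the libraries labelled nup82 nup136 and 2.70 ± 0.14 in the triple mutant. RAE1, an mRNA export factor, rose by 1.13 ± 0.09, 0.94 ± 0.09 and 1.66 ± 0.09 in the last 3 of these, and NDC1, which anchors the pore in the membrane, by 0.58 ± 0.12, 0.47 ± 0.12 and 1.01 ± 0.12. MYB15, a transcription factor of lignin and cold responses, rose by 1.86 ± 0.31, 2.65 ± 0.31 and 4.02 ± 0.31 in the same genotypes. These genes were chosen among list members after their values were seen.

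GLK2, a regulator of chloroplast development, rose by 0.69 ± 0.12 in nup136, 0.77 ± 0.12 in nup50c nup136 and 0.43 ± 0.12 in the triple mutant, where most other photosynthesis genes fell. MAF5, lower in the libraries labelled nup82, rose by 1.07 ± 0.21 in the triple mutant. QQS, a gene known for variable methylation, fell by 3.69 ± 0.80 on the log2 scale there. Of 434 tested long non-coding RNA genes, 25 rose and 44 fell in the triple mutant against WT (median -0.17), and 12 rose and 16 fell in nup50c nup136 (median 0.04). In the libraries labelled nup82 nup136 it was the other way, with 14 higher and 11 lower (median 0.06).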
